A study of Homo sapiens with 4 samples.

How the data were processed

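RBE is an established human intrahepatic cholangiocarcinoma cell line, a cancer of the bile ducts inside the liver. RNA was sequenced from RBE cells carrying a short hairpin RNA against LARS1, which encodes cytosolic leucyl-tRNA synthetase, the enzyme that loads leucine onto its tRNAs, and from control cells (NC), which the labels call wild type and the file headers name as a control hairpin. From each cell state there was 1 input library, made from total RNA, and 1 RNC library, made from mRNA bound to ribosomes with a nascent chain. How these complexes were isolated is not given in the sources used here. The 4 samples therefore form 4 groups of 1 library. No group had a replicate, so no test across samples was made and no p-value is given. Differences are described by their size, and whether they exceed the variation between cultures was not measured.

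Gene expression in FPKM, which relates fragments to transcript length and to the mapped fragments of the library, was computed by the authors, per the file headers. Whole-number counts per gene were also deposited by the authors, without normalization as far as the values show. Per the submitters' processing notes, TopHat2 and HTSeq were used with the genome build hg38. These notes give neither versions nor roles, and the program that computed FPKM is not given in the sources used here. The library kit marks the strand of the RNA, per the labels' protocols. Whether the counting used the strand, and which program made the counts, is not given in the sources used here. Of the genes compared, 17 of 62 with FPKM and 6 of 17 with counts overlap a coding gene on the opposite strand in GENCODE 29, and their values are uncertain in that respect. Those named below with FPKM are ACSM3, ARF5, BAD, C1orf112, CIAPIN1, DBNDD1, GCFC2, LIG3, M6PR, MCUB, RECQL and REXO5. Those named below with counts are CCT3, LRRC26, MRPL49 and TSACC. If counts were estimated from coverage, their counting intervals are approximate.

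The FPKM values analysed here cover 99 genes and the counts cover another 99 genes. The tables share 0 genes. Totals of the counts are sums over those genes and not library depths, and the sequencing depth behind the FPKM values is unknown. Among 8 genes below 0.2 FPKM in both inputs, at best 50.0% of the ratios between the inputs came within 1% of a ratio of whole numbers up to 6, which equalled the median of 50.0% for 200 random sets. Reads were therefore not recovered from FPKM. The columns of the knockdown libraries name a hairpin by number rather than by gene. They were assigned to the LARS1 knockdown because it is the only knockdown the labels give, and the names match the cell line and the fraction. LARS1 itself was not analysed here, so the strength of the knockdown was not checked.

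Before the data were examined, the 2-fold size, the filter of 1 FPKM, the named-gene rule and 30 gene lists were fixed. The limit of 25% used for close values was not part of that plan. Neither were the minimum mean of 50 counts, the scaling of the counts and the allowance of 3 counts. The plan gave preference to counts relative to library totals (CPM) if the counts covered at least as many genes as FPKM. This was not followed, because CPM needs library totals. FPKM is therefore the main measure, and the counts are described separately. For FPKM, each difference is log2 of 1 value plus 0.1 over another value plus 0.1, which understates the change of low genes. A gene entered a comparison at 1 FPKM or more in at least 1 of the libraries compared, and a size of 2-fold was used for the gene counts. The change in the RNC-to-input ratio is the log2 RNC-to-input ratio in knockdown cells minus that in control cells. The rule allowed any gene to be named where a table held fewer than 100 genes, which applied to both. List medians required 5 measured members. No list reached this (9 of the 30 lists had 1 member each), so members are given singly. Single-gene results for 2 of the genes measured are not reported here.

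For the counts, 17 genes with a mean of 50 or more counts per library were compared. These counts were scaled by the median over those genes of the log2 count minus the gene's mean, computed for each library. Of the 99 gene identifiers, 99 matched the gene name reference, and 34 of these have no symbol there. Intervals are 95% exact Poisson intervals for counts and exact conditional binomial intervals for ratios of 2 counts. For the change in the RNC-to-input ratio they are normal intervals on the log scale. They cover counting error only, without the scaling factors, and reads without molecular identifiers are not independent molecules. A count of 0 was treated as allowing up to 3 counts.

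Coding sequences and gene positions for overlap checks came from GENCODE release 29 (GRCh38). All 99 FPKM identifiers were found there, but only 25 had the same start and end, so the spans of the other genes are not those of release 29. Coordinates printed for FPKM genes are those of the deposited table. The share of each amino acid's codons was taken from the longest complete coding sequence per gene, found for 62 of the 62 genes at 1 FPKM or more in any library. Correlations across genes are Spearman coefficients with intervals from 2000 bootstrap resamples of genes. Genes are not independent replicates.

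The functions were tested on simulated data drawn from the control input values with 20 genes changed in the knockdown RNC library, without variation between cultures. A depth of 100 reads per FPKM was assumed, since the real depth is unknown, and the recovery depends on it. A gene counted as recovered at 0.75 of the simulated log2 change. In the RNC comparison, 19 of 20 were recovered with 4-fold changes on 59 genes and 19 of 20 with 2-fold changes on 60 genes, with 0 others called. For the change in ratio it was 19 of 20 on 60 genes and 18 of 20 on 61 genes. The gene counts in the results use the full 2-fold size, and most real RNC values were lower than input values. The recovery therefore does not give the sensitivity of those gene counts. The scaling of the counts, the codon correlations and the random gene sets were not simulated. The exact Poisson interval held the true count in 95.6% of draws. Alternatives were other pseudocounts (0.5 and 1), other filters, and scaling by the median, the median ratio or the upper quartile. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9.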

Results

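Input RNA and ribosome-nascent chain complex (RNC) RNA were compared between RBE cholangiocarcinoma cells with a hairpin against LARS1 and control (NC) cells, with 1 library of each kind and no replicates. The design asked which genes are translated differently after the knockdown. Of the 99 genes with FPKM values, 62 reached 1 FPKM in at least 1 library and 9 were listed at 0 in all 4. Genes at 1 FPKM or more numbered 59 in the NC input, 42 in the NC RNC, 62 in the shLARS1 input and 45 in the shLARS1 RNC library. The other 99 genes had counts, of which 59 had 0 counts in every library and 17 had a mean of 50 or more. Their totals were 165890 in the NC input, 178265 in the NC RNC, 154760 in the shLARS1 input and 166237 in the shLARS1 RNC library. CCT3, a subunit of the cytosolic chaperonin, took between 54.8% and 63.0% of these totals.

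For the 62 genes compared, the input libraries, which measure transcript level, differed little between cell states. This does not extend to the genes not analysed here, LARS1 among them. In 54 of 62 genes the higher value exceeded the lower by less than 25%, and 0 genes were 2-fold higher or lower. The median log2 difference was 0.01 with a middle range of −0.09 to 0.08. The lowest values relative to control were those of PRKAR2B, a regulatory subunit of protein kinase A, at −0.50, and NDUFAB1, the mitochondrial acyl carrier protein, at −0.43. NDUFAB1 (chromosome 16, 23581014 to 23596316, hg38) was at 46.9 FPKM in control and 34.8 FPKM in knockdown cells. COPZ2, a subunit of the coatomer of Golgi vesicles, stood at −0.37, and M6PR, the receptor that carries lysosomal enzymes by their mannose phosphate tag, at −0.32. The highest were ACSM3, a mitochondrial fatty acid–CoA ligase, at 0.46, C1orf112 at 0.36, DVL2, a component of Wnt signalling, at 0.35, and VPS50 and GCFC2 at 0.34 each. The abundant SLC25A5, the mitochondrial ADP/ATP carrier, was at 520 FPKM in control and 516 FPKM in knockdown input.

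Among the 17 genes compared by counts, 1 differed 2-fold in input. CDC42EP2, an effector of the small GTPase CDC42, had 1679 counts (95% interval 1600 to 1761) in control and 748 counts (695 to 804) in knockdown input. Its scaled log2 difference was −1.16 (95% counting interval −1.29 to −1.04), or 2.24-fold lower, while in RNC RNA it was −0.28 (−0.39 to −0.17). A second coding gene model overlaps CDC42EP2 on its strand in GENCODE 29, so its counts are uncertain. In 15 of the 17 genes the input values were within 25%, among them CCT3 at −0.09 (−0.10 to −0.07) and ARPC2, a subunit of the actin-nucleating Arp2/3 complex, at −0.13 (−0.15 to −0.11). TSACC at 0.42 (0.09 to 0.75) was the other exception. TSACC lies within the span of CCT3 on the opposite strand, so without a stated use of strand the reads of this pair cannot be told apart.

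The RNC libraries, the comparison named by the design, differed more from gene to gene than the inputs, over fewer genes and at lower values. For genes at 1 FPKM or more in all libraries, medians were 9.65 FPKM in NC input and 8.62 FPKM in shLARS1 input. In NC RNC and shLARS1 RNC they were 5.83 and 4.53 FPKM. Whether the wider spread comes from the knockdown or from error in single RNC libraries was not tested. Of 47 genes, 33 were within 25%, 2 were at least 2-fold higher in knockdown cells and 0 were 2-fold lower. The median log2 difference was −0.07. The 2 genes were CYP51A1, the lanosterol demethylase of cholesterol synthesis, at 3.85, and RECQL, a DNA helicase, at 1.06. CYP51A1 (chromosome 7, 92084987 to 92134503, minus strand, hg38) was listed at 6.25 FPKM in NC input, 0.068 FPKM in NC RNC, 5.79 FPKM in shLARS1 input and 2.33 FPKM in shLARS1 RNC. The difference therefore rests on the low value of the control RNC library. In addition, 2 coding gene models overlap CYP51A1 on the same strand in GENCODE 29, AC000120.2 and AC000120.3, and neither was analysed here. With a pseudocount of 1 its log2 difference was 1.64. RECQL (chromosome 12, 21468910 to 21501669, hg38) was at 1.37 FPKM in control and 2.96 FPKM in knockdown RNC. Its log2 difference was 0.89 with a pseudocount of 0.5 and 0.74 with 1, which is below 2-fold, and the coding gene PYROXD1 overlaps it on the opposite strand.

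Further genes above control in RNC RNA were GCLC, the catalytic subunit for glutathione synthesis, at 0.67, RPAP3, a cofactor of RNA polymerase assembly, at 0.66, ACSM3 at 0.58 and TSPAN6 at 0.49. GCLC was at 0.891 FPKM in control and 1.48 FPKM in knockdown RNC. Low values were those of COPZ2 at −0.84, NDUFAB1 and DBNDD1 at −0.49 each, and LASP1, an actin-binding protein, and CIAPIN1 at −0.42 each. LASP1 was at 118 FPKM in control and 87.9 FPKM in knockdown RNC. NDUFAB1 and COPZ2 stood below control in both input and RNC, and GCLC and ACSM3 above control in both, under each scaling tried. The RNC difference of NDUFAB1 shrank to −0.03 after upper-quartile scaling, which is close to no difference. Scaling moved the medians of all genes. The RNC median of −0.07 became 0.10 after centring on the median ratio, 0.29 after centring on the median and 0.39 after scaling to the upper quartile, and the input median of 0.01 became 0.07, 0.16 and 0.13. Genes at least 2-fold higher in RNC numbered 4 after centring on the median, with GCLC and RPAP3 added, and 5 after upper-quartile scaling, with ACSM3 added, where LASP1 and CIAPIN1 stood at 0.04 each.

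**Figure D1:**
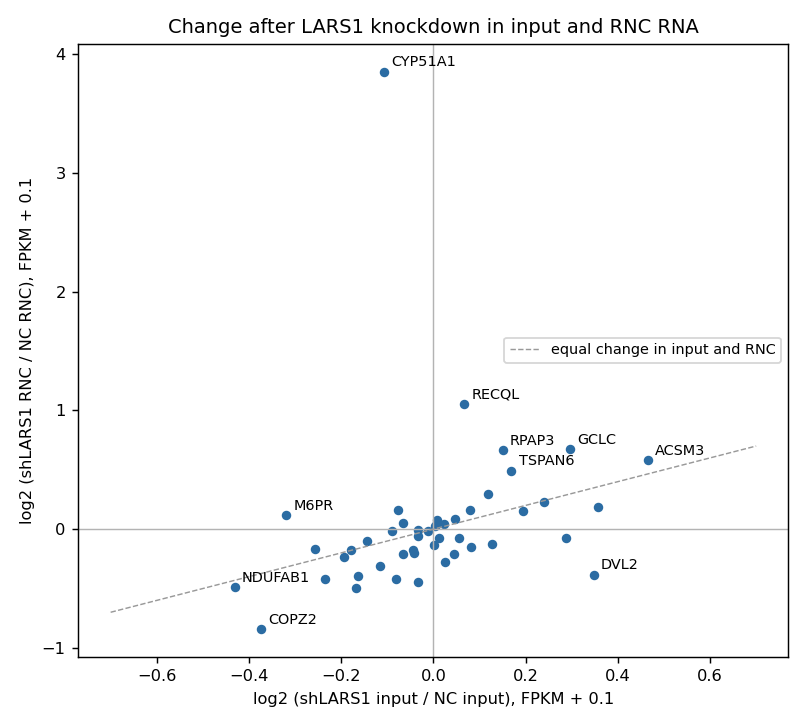
Log2 difference between knockdown and control cells in input RNA (x axis) and in RNC RNA (y axis) for the 47 genes at 1 FPKM or more in an RNC library, each point 1 gene, with 1 library per group and no error bars. CYP51A1 at 3.85 and RECQL at 1.06 lie apart from the other genes on the y axis, while the largest value on the x axis is that of ACSM3 at 0.46.

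Among the counts, 0 of 17 genes differed 2-fold in RNC RNA. The farthest from 0 was PXK, a protein with a kinase-like domain, at −0.85 (−1.22 to −0.49), with 182 counts in control and 98 counts in knockdown RNC. MRPL49, a mitochondrial ribosomal protein, was at −0.37 (−0.48 to −0.26) in RNC and −0.27 (−0.34 to −0.21) in input. The intervals of 11 of the 17 genes excluded 0 in RNC, which concerns counting error in these libraries and not the spread between cultures. RGPD6, at 0.12 (−0.28 to 0.53), belongs to a family of near-identical genes and is uncertain for that reason.

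**Figure D2:**
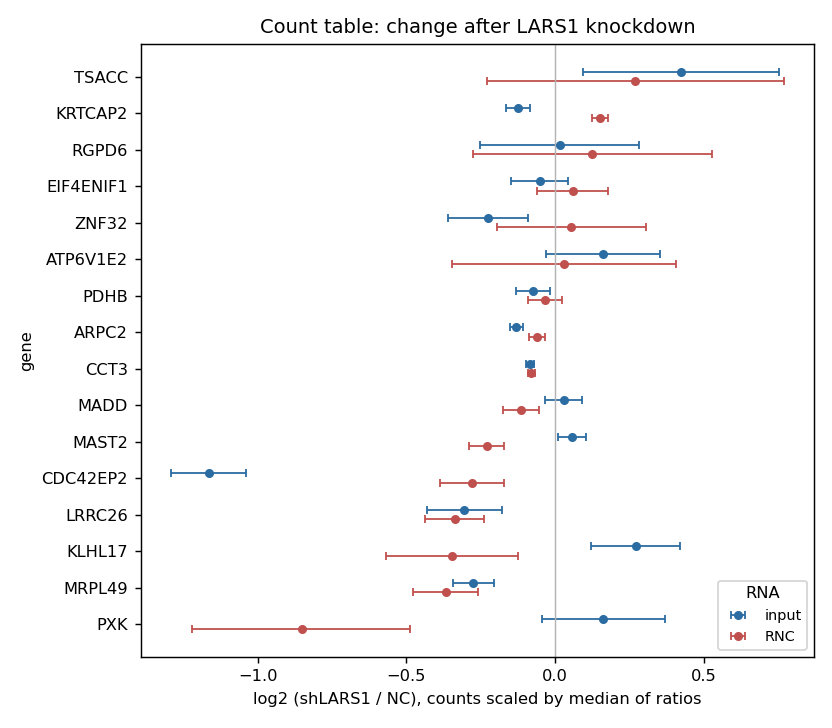
Log2 ratio of knockdown to control counts on the x axis for 16 genes with a mean of 50 or more counts, in input (blue) and RNC (red), with bars for 95% counting intervals. CDC42EP2 in input (−1.16) and PXK in RNC (−0.85) lie farthest from 0.

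N-glycosylation genes fixed in the lists before the data were examined were represented by KRTCAP2 and DPM1. KRTCAP2, a subunit of the oligosaccharyltransferase that transfers glycans to asparagine, had 10620 counts in control and 9728 counts in knockdown input, a scaled log2 difference of −0.12 (−0.16 to −0.08). In RNC it had 20212 and 21771 counts, a difference of 0.15 (0.12 to 0.18), and its RNC-to-input ratio was higher by 0.27 (0.23 to 0.32). The RNC difference was 0.11 without scaling and 0.21 when scaled by the total. A second coding gene model also overlaps KRTCAP2 on its strand. DPM1, a subunit of the enzyme that makes dolichol-phosphate mannose, was at 1.31 FPKM in control and 1.07 FPKM in knockdown input (log2 −0.28), and at 0.589 and 0.494 FPKM in RNC (−0.21, below the 1 FPKM filter). This RNC difference of DPM1 turned to 0.10 after centring on the median and 0.18 after upper-quartile scaling.

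Other fixed lists had at most 1 member each. BAD, a promoter of apoptosis, was at 36.5 and 34.8 FPKM in input (−0.07) and 28.2 and 24.4 FPKM in RNC (−0.21), control first. After centring on the median these differences of BAD turned to 0.10 and 0.16. CCT3, from the chaperone list, was at −0.08 (−0.09 to −0.07) in RNC. CFTR, a chloride channel of bile duct epithelium, was listed at 0.003 FPKM in the NC input and at 0 in the other libraries. The histone gene H1-4 had between 10 and 13 counts per library. The 21 lists without a member, among them the tRNA synthetases, the ATF4 response and the unfolded protein response, were not analysed here.

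The RNC-to-input ratio, a measure of how much of a transcript is bound to translating ribosomes, was below 1 for most genes in both cell states in the values as deposited, but not under every scaling. The median log2 ratio was −0.56 over 59 genes in control cells and −0.72 over 62 genes in knockdown cells. The gap between them does not measure the change per gene, which had a median of −0.04 over 62 genes. FPKM is relative to each library, so these medians do not measure total translation. In control cells 19 genes were 2-fold lower and 0 were 2-fold higher in RNC than in input, and in knockdown cells 20 and 0. After centring on the median, 6 genes were 2-fold higher and 3 lower in control cells and 7 and 2 in knockdown cells, and the medians became 0.12 and 0.19. After upper-quartile scaling the splits were 6 and 3 in control and 12 and 1 in knockdown cells, with medians of 0.14 and 0.33. The FPKM ratios of single genes that follow are unscaled. They are to be read against the medians of −0.56 and −0.72 rather than against 0. High ratios in both cell states belonged to WDR54 at 0.54 in control and 0.51 in knockdown cells, to ARF5, a small GTPase of the Golgi, at 0.48 and 0.56, to FKBP4, a cochaperone of HSP90, at 0.40 and 0.44, and to NDUFAB1 at 0.38 and 0.32. Low ratios belonged to MCUB, a subunit of the mitochondrial calcium uniporter, at −1.87 and −1.51, to LAP3, a leucine aminopeptidase, at −1.49 and −1.38, and to CROT, a peroxisomal acyltransferase, at −1.42 and −2.13. MCUB and CROT were below 1 FPKM in both RNC libraries. Ratios in the 2 cell states, which share no library, correlated across 62 genes with a Spearman coefficient of 0.873 (bootstrap interval 0.790 to 0.921), and across the 17 genes with counts with 0.848. These are correlations across genes, which are not independent replicates. In the counts, KRTCAP2 had 1.60 in control and 1.88 in knockdown cells, LRRC26 1.39 and 1.35, and CCT3 0.98 and 0.99, each relative to the scaling of the 17 genes. Without scaling KRTCAP2 had 0.93 and 1.16, LRRC26 0.71 and 0.64, and CCT3 0.30 and 0.27. A second coding gene model overlaps LRRC26, and another overlaps ARF5, on the same strand. By scaled counts 2 genes were 2-fold higher and 2 lower in control cells and 3 and 2 in knockdown cells, against 0 and 7 and 1 and 7 without scaling.

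**Figure D3:**
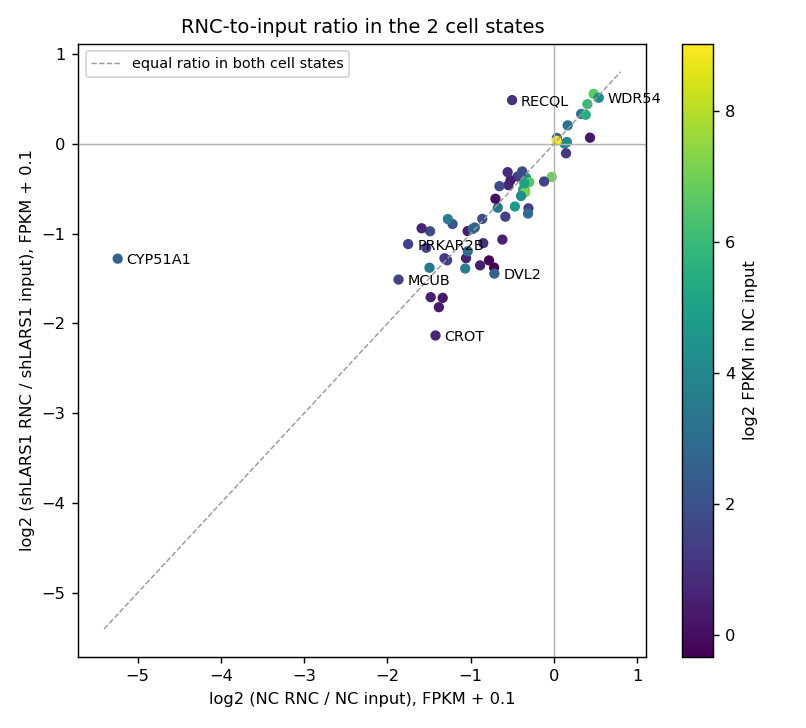
Log2 RNC-to-input ratio in control cells (x axis) and knockdown cells (y axis) for 62 genes, coloured by log2 FPKM in the control input, with 1 library per group and no error bars. Most genes follow the dashed line of equal ratios, and CYP51A1 (−5.24 in control, −1.28 in knockdown cells) lies far from it.

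The change in the RNC-to-input ratio after the knockdown was within 25% for 40 of 62 genes, and the median log2 change was −0.04, with 27 genes above 0 and 35 below. The sign of this median turned under each scaling, to 0.06 after centring on the median ratio (34 genes above 0 and 28 below), 0.16 after centring on the median (42 and 20) and 0.29 after upper-quartile scaling (50 and 12). CYP51A1 at 3.96 was the only gene with a 2-fold higher ratio, and 0 were 2-fold lower. RECQL stood at 0.99, and at 1.09 after centring on the median ratio, where 2 genes were 2-fold higher. Next were REXO5 at 0.65, PRKAR2B at 0.63, RPAP3 at 0.51 and M6PR at 0.44. The most negative were DVL2 at −0.73, CROT at −0.71, VPS50 at −0.66 and GCFC2 at −0.52. REXO5, PRKAR2B, CROT, VPS50 and GCFC2 were below 1 FPKM in both RNC libraries. They entered through their input values, and their RNC values are low and uncertain. For PRKAR2B (−0.50 in input, 0.13 in RNC), GCFC2 (0.34 and −0.18) and M6PR (−0.32 and 0.12) most of the change came from the input. VPS50 (0.34 and −0.32) drew on both. For REXO5 (−0.09 and 0.55) and CROT (0.11 and −0.60) most came from RNC. DVL2 was at 5.91 FPKM in control and 7.55 FPKM in knockdown input, and at 3.56 and 2.71 FPKM in RNC. Among the counts, PXK at −1.01 (−1.42 to −0.60) was the single gene at 2-fold, and CDC42EP2 at 0.88 (0.72 to 1.05) had the largest positive change. CDC42EP2 lay below control in both fractions, at −1.16 in input and −0.28 in RNC, so its ratio was higher because the input was lower still. Codon use was examined because LARS1 charges leucine tRNAs. Across 62 genes the share of leucine codons and the change in ratio had a Spearman coefficient of 0.0067 (bootstrap interval −0.257 to 0.255) and a Pearson coefficient of 0.119. At 5 FPKM or more, a filter chosen for this coefficient after the data were seen, it was 0.428 (0.057 to 0.714) across 28 genes. For the 34 genes at 1 to 5 FPKM the Spearman coefficient was −0.165.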

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

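No test was made for the results in this part, and the scalings given beside these genes were chosen after the data were seen. For RECQL, LIG3 and MAST2 the RNC library lay above the input in 1 cell state and below it in the other, with 1 library on each side, so the difference was not tested. RECQL had a log2 RNC-to-input ratio of −0.50 in control and 0.49 in knockdown cells, a change of 0.99. After centring on the median its ratios were 0.18 and 1.38, so the opposite signs depend on the scaling. LIG3, a DNA ligase, had 0.15 and −0.11, a change of −0.25, and 0.48 and 0.33 after centring on the median ratio. After upper-quartile scaling its ratios were 0.86 and 0.93, so the direction of its change depends on the scaling as well. By scaled counts, MAST2 had 0.15 and −0.13, a change of −0.29. Without scaling it lay below the input in both states, at −0.52 and −0.85.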

How the results depend on the processing

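Centring on the median ratio, leaving out CYP51A1, the alternatives for the leucine coefficient and the median ratios, the scalings of the counts and each alternative for a single named gene were chosen after the data were seen. CPM (library totals not known), the LARS1 values (LARS1 was not analysed here) and the medians of gene lists (fewer than 5 members each) were not run. No paired analysis was possible because each group held 1 library. Of the alternative values that answer a comparison, 53 stayed close to the reported value and 35 moved, close meaning within 1.5-fold for gene counts and medians and within the bootstrap interval for the leucine coefficient. For 16 differences of named genes with FPKM, 75 of 80 alternative log2 values lay within 1.5-fold of the reported one, a tolerance wide enough to let small differences shrink to near 0, as for NDUFAB1 in RNC (−0.03 with the upper quartile), and 2 turned sign, both for DPM1 in RNC. Outside these 16, BAD, LASP1, CIAPIN1 and DVL2 were among the genes whose RNC difference turned sign under a scaling. For named genes with counts, 10 of 18 lay within the narrower counting interval. With every gene above 0 kept, 1 gene was 2-fold lower in input, 1 was lower in RNC, 2 were higher and 3 lower in the change of ratio, and 1 was higher in control RNC over input. Genes 2-fold higher in RNC (2 as reported) numbered 1 with a pseudocount of 0.5, 1 with a pseudocount of 1, 1 with 1 FPKM required in both libraries, 0 with a filter of 5 FPKM, 4 after centring on the median and 5 after upper-quartile scaling. Higher genes in the change of ratio (1 as reported) numbered 0 with 1 FPKM required in all libraries, 0 without CYP51A1, and 2 after centring on the median ratio, on the median or scaling to the upper quartile. For control RNC over input, lower genes (19 as reported) numbered 6 with a pseudocount of 1, 6 with 1 FPKM required in both libraries, 5 with a filter of 5 FPKM, 11 centred on the median ratio, 3 centred on the median and 3 with the upper quartile, and higher genes (0 as reported) numbered 6 under each of the last 2 settings. For knockdown RNC over input, lower genes (20 as reported) numbered 12 and 6 with pseudocounts of 0.5 and 1, 7 with 1 FPKM required in both libraries, 5 with a filter of 5 FPKM, 7 centred on the median ratio, 2 centred on the median and 1 with the upper quartile, and higher genes (0 as reported) numbered 1, 7 and 12 under the last 3. The leucine coefficient was 0.428 at 5 FPKM or more. Stricter filters compare fewer genes by construction, and for the other settings the cause was not tested. Depth is unknown for FPKM, so genes of low FPKM such as RECQL carry an unmeasured counting error.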

Other observations

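Both tests on CYP51A1 and the test of single-library noise were chosen after the results were seen, as were the gene groups, the low-count genes, and the proline and expression-split coefficients.

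Genes sharing an annotation in the deposited table were compared by the median of their log2 RNC-to-input ratio with 10000 random gene sets of the same size, matched in 5 bins of mean expression. Of 9 terms with 10 or more genes, from which the broad term protein binding is left out, mitochondrion (12 genes) had medians of −0.34 in control and −0.36 in knockdown cells, at the 78.8 and 90.9 percentiles. Cytoplasm (24 genes) had −0.43 and −0.50, at the 90.5 and 89.3 percentiles, and cytosol (16 genes) −0.88 and −1.05, at the 16.5 and 12.8 percentiles. Integral membrane proteins (12 genes) had −0.79 and −0.87, at the 10.5 and 9.96 percentiles. In the change of ratio, extracellular exosome (10 genes) was at the 99.1 percentile with a median of 0.06, the farthest from the middle of 9 terms in 3 comparisons. SAA2-SAA4, a read-through transcript of serum amyloid genes that shares sequence with SAA2 and SAA4 and is uncertain for that reason, had 130 counts in control and 50 in knockdown input. This was 2.6-fold lower after scaling, but the gene is not among the 17 compared because its mean was below 50 counts. It had 0 counts in control RNC, which allows up to 3, and 18 counts (95% interval 10.7 to 28.4) in knockdown RNC. SEPTIN5 had 21 and 44 counts in control and knockdown input and 0 in both RNC libraries.

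CYP51A1 was listed 37.7-fold lower in control RNC than in control input on the scale with 0.1 added, against 2.43-fold in knockdown cells. Counting noise at its expression level is argued against, since among 16 other genes at 3 to 12 FPKM in control input the largest change in ratio was 0.73 in size, that of DVL2. Reads assigned to another gene model at the same locus stay open as a cause, since 2 coding models overlap the gene on its strand and neither was analysed here. The overlap is the same for every library, so by itself it gives no reason for a low value in control RNC only. A real effect of the knockdown on this mRNA stays open as well, since there is 1 library of each kind.

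The RNC-to-input ratio varied between genes in nearly the same order in both cell states, with a Spearman coefficient of 0.873, which argues against noise of single libraries. Abundance in the input followed the ratio, with coefficients of 0.440 in control and 0.456 in knockdown cells, so that abundant genes had higher ratios. GC content of the coding sequence (0.357 and 0.224) and transcript length (−0.279 and −0.250) stay open, since for both the interval in knockdown cells includes 0. Whether abundance itself plays a role, through translation or through the enrichment of RNC libraries, stays open. No biological explanation was tested. Scaling by a single factor per library shifts all ratios nearly alike, so it would leave these rank coefficients almost unchanged.

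The hypothesis that genes rich in leucine codons lose ribosome-bound mRNA when LARS1 is depleted predicts a negative coefficient between leucine codon share and the change in ratio. The value was 0.0067 with an interval of −0.257 to 0.255 over 62 genes, which is too wide to exclude a modest relation of either sign. At 5 FPKM or more it was 0.428 (0.057 to 0.714, 28 genes; Pearson 0.295; 0.373 without CYP51A1), opposite to the prediction, and at 1 to 5 FPKM it was −0.165 (34 genes). The sign bears on this hypothesis only and not on other effects of leucine codons. RNC RNA measures bound mRNA and not the speed of the ribosomes on it. In those 28 genes the coefficient with the input difference, which enters the change in ratio with a minus sign, was −0.251, so part of the 0.428 may come from the input. Of the 20 amino acids, proline had the coefficient farthest from 0, at −0.358 (−0.576 to −0.113), which may be a chance maximum of 20 coefficients.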
